A study of Arabidopsis thaliana with 12 samples.

How the data were processed

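Reads were aligned to the TAIR10 genome with TopHat2 2.1.1 and Bowtie2 2.3.2.0, and expression was estimated with Cufflinks 2.2.1 and Cuffdiff, whose version was not given, per the submitters' processing notes. The annotation was Araport11, per the file headers of the read report. The FPKM values (mapped fragments scaled to transcript length and library depth) were computed by the authors for 27655 genes in each of 12 libraries, per the file headers. Scaling factors between libraries computed from these values lay between 0.980 and 1.02, and the authors' notes named no normalization beyond FPKM. The median FPKM of the genes tested below was 11.6 to 11.9 in each library. Whether the values already held a normalization between libraries was not recorded, so depth may not be their only scaling. The authors deposited a second table of 313 genes with their mean FPKM per genotype. Its log2 columns were the authors' ratios of those means to the WT mean without a pseudocount, per the file headers. The p-value columns of that table held the authors' adjusted values, and no file named the test behind them. The read report gave the numbers of reads before and after trimming and of mapped reads per library, and the mapped fraction was deposited by the authors in the same report. Read counts per gene were not used here, so the counting error of single genes was unknown.

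The libraries were made with a stranded mRNA kit and sequenced as pairs of 75 bp reads, per the labels' protocols. Library names follow the titles. The genotype entry of ccrfer replicates 2 and 3 named other fer allele numbers than that of replicate 1, and the titles were used. Gene symbols came from a reference table of assembly TAIR10.1, in which 27445 of the 27655 identifiers had an entry. That table served only for symbols and for the order of neighbouring genes. A gene is given by its identifier where the table held no symbol, and the symbols of list members are those of the table (IRX12 for LAC4, IRX3 for CESA7, IRX1 for CESA8, TCH4 for XTH22, PAP1 for MYB75).

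From the FPKM values, log2(FPKM + 1) was computed, and the 18428 genes at FPKM 1 or more in at least 3 libraries were tested. The pseudocount understates differences of genes at low FPKM. limma 3.58.1 in R 4.3.3 was fitted over all 12 libraries with a mean per genotype and no block for the replicate number, with empirical Bayes moderation that allowed a trend with mean expression. Tests were two-sided, and p was adjusted by Benjamini and Hochberg over the tested genes of each comparison. Genes with an adjusted p under 0.05 are called higher or lower. Differences are on the log2(FPKM + 1) scale, SE is the standard error of that fit, and means are given with the SD of 3 libraries. Adjusted p values of genes come from limma.

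The comparisons were ccr with WT, ccrfer with ccr, fer with WT, ccrfer with fer, ccrfer with WT, and the interaction, which is the ccrfer minus fer difference less the ccr minus WT difference. The replicate numbers did not pair the libraries. After removal of genotype means, 18 pairs of libraries with the same number correlated between -0.129 and 0.191, with a median of 0.016.

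The comparisons, the tests, the gene lists and the rule for named genes were chosen before the data were examined. The 23 lists were lignin biosynthesis, secondary wall cellulose and xylan, primary wall and cell expansion, pectin modification, flavonoid and anthocyanin, salicylic acid and systemic acquired resistance, pattern-triggered immunity, cysteine-rich receptor-like kinases, wall-associated kinases, FERONIA family and partners, calcium sensors and channels, jasmonate, ethylene-jasmonate defence, glucosinolate biosynthesis, abscisic acid, cold and drought, heat shock, senescence, photosynthesis, phloem markers, cambium markers, epidermis markers, flower and pollen markers, and seed and silique markers. No gene stood in more than 1 list. The camera test of limma compared each list with the other tested genes at a preset correlation of 0.01, with p adjusted over the 22 lists that had at least 3 tested genes. Camera with an estimated correlation and fry, which tests the genes of a list without regard to other genes, were run beside it.

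The named genes were CCR1 and FER, the 10 genes with the largest difference each way in ccr against WT and in ccrfer against ccr, and 5 each way in the other comparisons. These had libraries of the compared genotypes that did not overlap, a condition not set for the interaction, and a mean FPKM of 5 or more in the higher genotype. Added to them were up to 4 members of each list, and the genes that moved most up and then down, or down and then up, across WT, ccr and ccrfer. The genes next to FER, AT2G01021, genes listed at 0 and those taken from the deposited table were chosen after their values were seen.

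Normal log2(FPKM + 1) values were simulated for the 18428 genes, with the same spread in all genotypes. Changes were put only into genes with a mean above 2 on that scale. The recovery therefore does not cover lower genes or the wider spread of ccrfer. With 100 genes changed by a log2 difference of 1, the fit recovered 82% in ccr against WT, 83% in ccrfer against ccr, 90% in fer against WT, 82% in ccrfer against fer and 83% in ccrfer against WT. With 100 genes changed by 2 on the log2 scale it recovered 95%, 98%, 97%, 96% and 99% in the same order, with at most 9 false calls in a comparison. In the simulated interaction 93.5% of 200 genes were recovered. Figures were drawn with matplotlib 3.10.9.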

Results

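Messenger RNA of main inflorescence stems of Arabidopsis thaliana was sequenced from 2-month-old plants of 4 genotypes, with 3 biological replicates each. The genotypes were Col-0 wild type (WT), ccr1-3 (ccr), a mutant of the lignin gene CCR1 (cinnamoyl-CoA reductase), fer4 (fer), a mutant of the receptor kinase gene FERONIA (FER), and the double mutant (ccrfer). The question given with the series was how far loss of FERONIA alters genes that are up in ccr1-3. Libraries held 56884740 to 227159338 reads, and 52612839 to 210590409 reads of a library were mapped. The mapped share was 91.4% to 94.2%. The smallest library was fer replicate 2 and the largest ccr replicate 2. Of the 27655 genes, 6064 (ccr replicate 2) to 9582 (ccrfer replicate 3) were listed at FPKM 0 in a library.

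Across the tested genes, libraries of a genotype correlated at r values of 0.991 to 0.992 in WT, 0.992 to 0.993 in ccr, 0.968 to 0.978 in fer and 0.938 to 0.983 in ccrfer. Libraries of different genotypes correlated at 0.845 to 0.954. The first principal component held 43.9% of the variance and parted the WT libraries (-75.0 to -73.4) from the 9 mutant libraries (0.56 to 45.0), so WT stood apart from all 3 mutants. ccrfer replicate 3 stood apart from the other ccrfer libraries on the component that held 15.5% of the variance, at 65.6 against 9.48 and 16.0. AT2G01021, which lies beside the 5.8S ribosomal RNA gene in the reference order, had an FPKM of 45932600 in ccrfer replicate 3. It was at 15147300 in fer replicate 2, 8613970 in fer replicate 3, 6128100 in ccrfer replicate 1 and 1429630 in fer replicate 1, and lay between 42536.3 and 410312 in the other libraries. The 1st percentile of the FPKM values above 0 lay between 0.0207 in ccr replicate 2 and 0.543 in ccrfer replicate 3.

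FER (AT3G51550) was nearly absent from the double mutant and at the WT level in the libraries labelled fer. Its FPKM was 85.9, 83.5 and 83.0 in WT, 100.4, 97.7 and 96.5 in ccr, 85.1, 83.1 and 84.0 in the libraries labelled fer, and 0.894, 0.159 and 1.49 in ccrfer, in the order of the replicates. FER was lower in ccrfer than in ccr by -5.82 (SE 0.197, adjusted p = 1.75e-09, lower in 3 of 3 libraries), while fer minus WT was 0.00 (adjusted p = 0.997). FER expression therefore goes against the label fer, and directions drawn from these 3 libraries are given as those of the libraries labelled fer. Genes close to FER on one side were nearly absent both from the libraries labelled fer and from ccrfer. DGAT2 (AT3G51520), a diacylglycerol acyltransferase gene placed 3 genes from FER, was at 23.7, 24.7 and 24.6 in WT and 18.6, 21.5 and 19.1 in ccr, against 0.374, 0 and 0 in the libraries labelled fer and 0.130, 0.0415 and 0 in ccrfer. AT3G51530 had a mean of 6.47 in WT and in ccr, was at 0.0316, 0 and 0 in the libraries labelled fer and was listed at 0 in ccrfer. AT3G51540, next to FER, was low in all genotypes, at 0.310 to 0.670 in the WT and ccr libraries and listed at 0 in the other 6. The next gene outward, AT3G51510, had means of 23.7 in WT, 20.5 in ccr, 28.7 in the libraries labelled fer and 36.5 in ccrfer. On the other side of FER, AT3G51560 was at 3.43, 4.17 and 4.05 in the libraries labelled fer and at 0 to 0.0452 in the other 9 libraries.

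CCR1 (AT1G15950) kept its transcript in ccr, with 236 ± 17.3 in WT, 199 ± 18.3 in ccr, 319 ± 30.2 in the libraries labelled fer and 206 ± 26.0 in ccrfer (FPKM, mean ± SD, n = 3). The ccr minus WT difference was -0.25 (SE 0.104, adjusted p = 0.0738). It passed the threshold with a replicate block (-0.25, adjusted p = 0.0298), without ccr replicate 1 (-0.32, adjusted p = 0.0429) and with median-of-ratios scaling (-0.28, adjusted p = 0.0431). CCR1 was called higher in the libraries labelled fer than in WT (0.43, adjusted p = 0.00422), a call lost after quantile normalization (0.20, adjusted p = 0.0871). It was called lower in ccrfer than in the libraries labelled fer (-0.63, adjusted p = 0.000474). Its interaction (-0.39, adjusted p = 0.0559) passed with the replicate block (0.0218), without WT replicate 1 (0.0463) and without ccrfer replicate 2 (0.0205). The ccrfer minus WT difference (-0.20, adjusted p = 0.13) passed without ccrfer replicate 2 (0.0413). Whether an insertion leaves a transcript that these values count was not recorded in the labels.

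**Figure D1:**
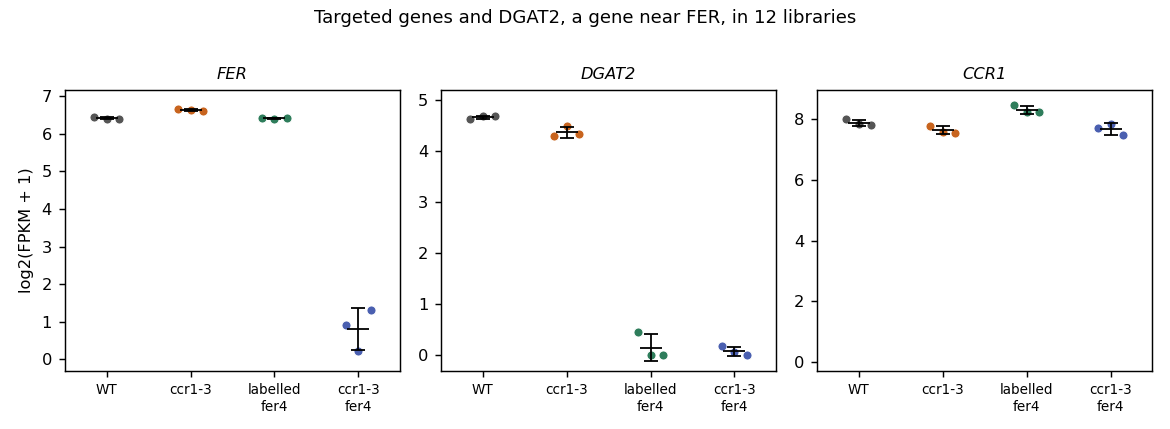
FPKM of CCR1, FER and DGAT2 on the log2(FPKM + 1) scale in each of the 12 libraries, with bars for the mean and SD of each genotype. FER lies between 83.0 and 100.4 FPKM in the WT, ccr and fer libraries and at most at 1.49 in ccrfer, while DGAT2 is at most at 0.374 in the fer and ccrfer libraries.

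The comparison of ccr with WT asks which genes the CCR1 mutation alters while FERONIA is intact. Genes of the woody cell wall were far higher in ccr stems. IRX3 (AT5G17420) and IRX1 (AT4G18780), cellulose synthases of the secondary wall, went from 1.44 ± 0.331 to 86.9 ± 3.04 and from 0.871 ± 0.0412 to 50.6 ± 0.933 (FPKM, mean ± SD, n = 3). FLA11 (AT5G03170), a fasciclin-like arabinogalactan protein of fibres, went from 2.24 ± 0.341 to 136 ± 2.85, and IRX12 (AT2G38080), a laccase that polymerizes lignin, from 1.27 ± 0.364 to 65.4 ± 3.22. The myrosinase genes TGG2 (0.518 to 94.2, log2 difference 6.02) and TGG1 (1.75 to 80.1, 4.88) and the latex protein gene MLP28 (1.42 to 90.2, 5.27) rose as well. Senescence genes fell, among them SAG12, the classic marker (327 ± 8.78 to 31.6 ± 1.45), and the nuclease gene BFN1 (29.0 to 0.889). The metacaspase gene MC9 (123 ± 5.08 to 3.16 ± 0.562) and the peptidase gene CEP2 (-4.81 on the log2 scale) fell too. The xylem protease gene XCP2, a member of the secondary wall list, was at 0.355 in WT and 18.9 in ccr. The iron superoxide dismutase gene FSD1 (75.5 to 0.596, log2 difference -5.60) and the phosphate-signalling gene SPX1 (211 to 6.11, -4.89) were also among the 10 largest decreases.

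Of 24 secondary wall cellulose and xylan genes, 22 rose in ccr and none fell, with a median difference of 3.08 (camera adjusted p = 6.09e-18). Lignin biosynthesis genes rose in 21 of 24 cases (median 1.64, adjusted p = 8.28e-15), including PER64 (4.19), LAC17 (3.13) and PAL4 (14.8 to 117 FPKM), the enzyme at the entry of the pathway. Of 15 primary wall and cell expansion genes 14 rose and 1 fell (median 1.19, adjusted p = 2.66e-08), led by the expansin genes EXPA10 (4.02) and EXPA1 (3.95 to 35.8 FPKM). All 7 cambium markers rose (median 0.71, adjusted p = 0.000409), with WOX4 at 2.52, HB-8 at 2.15 and PXY at 1.46. The lists that fell were senescence (11 of 15 lower and 1, HAI1, higher, median -1.15, adjusted p = 0.000126), wall-associated kinases (8 of 13 lower, adjusted p = 0.0012), flavonoid and anthocyanin (11 of 15 lower and 3 higher, adjusted p = 0.000268) and photosynthesis (15 of 30 lower and 2 higher, adjusted p = 0.0171). The photosynthesis call was lost with an estimated correlation (adjusted p = 0.581 with an estimated correlation) and after quantile normalization (adjusted p = 0.0653). The anthocyanin regulators MYB90 and PAP1 were at 9.26 and 20.0 FPKM in ccr against 93.8 and 68.4 in WT. The secondary wall, lignin, cambium and senescence lists moved in the same direction from WT in all 3 mutants, with WT the genotype that stood apart.

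Salicylic acid genes went both ways in ccr. PR1 (AT2G14610), the marker of salicylic acid signalling, rose from 0.608 ± 0.378 to 30.8 ± 2.15 (log2 difference 4.33, adjusted p = 8.32e-08, higher in 3 of 3 libraries), PR5 from 186 to 711, and UGT76B1 from 0.0341 to 3.45, while WRKY54 (-2.18) and ACD6 (-2.15) fell. Of the 29 salicylic acid genes 14 rose and 6 fell (adjusted p = 0.0879), a list that passed the threshold without the filter on low values (0.0282) and after quantile normalization (0.0412). Pattern-triggered immunity (11 higher and 6 lower of 28, adjusted p = 0.359), calcium sensors and channels (9 higher and 10 lower of 29, 0.533), cysteine-rich receptor-like kinases (3 higher and 8 lower of 20, 0.0979), FERONIA family and partners (5 higher and 4 lower of 14, 0.94), jasmonate (8 higher and 3 lower of 20, 0.0949) and ethylene-jasmonate defence (0 higher and 1 lower of 5, 0.607) were not called. Glucosinolate biosynthesis (11 higher and 5 lower of 20, 0.199) was not called although its regulator MYB29 rose by 3.20. Abscisic acid, cold and drought genes (7 higher and 6 lower of 21, 0.533) included P5CS1, the proline synthesis gene (5.88 ± 0.283 to 79.6 ± 2.18), and the drought regulator RD26 (8.26 to 32.9). Heat shock (2 higher and 3 lower of 7, 0.963), pectin modification (2 higher and 3 lower of 10, 0.298), phloem markers (3 higher and 6 lower of 9, 0.24), epidermis markers (4 higher and 2 lower of 8, 0.206) and seed and silique markers (3 higher and 0 lower of 10, 0.0785) were not called either. Without the filter on low values, cysteine-rich kinases (0.0272), jasmonate (0.0476) and seed and silique markers (0.0329) passed the threshold by camera, the last also with a pseudocount of 0.1 (0.0045). Flower and pollen markers had 1 tested gene and no list test.

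In all, 4416 genes were called higher and 3642 lower in ccr than in WT, of 18428 tested, and 1181 and 905 of them differed by at least 2-fold on the log2(FPKM + 1) scale. The libraries of ccr and WT did not overlap for 12712 genes (69.0%), against 10% by chance. Adjusted over the list alone, the counts of members were those given above except for secondary wall (23 higher), flavonoid and anthocyanin (4 higher), salicylic acid (15 higher and 7 lower) and calcium (10 higher and 11 lower). Leaving out any single WT or ccr library gave 6649 to 6854 called genes.

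**Figure D2:**
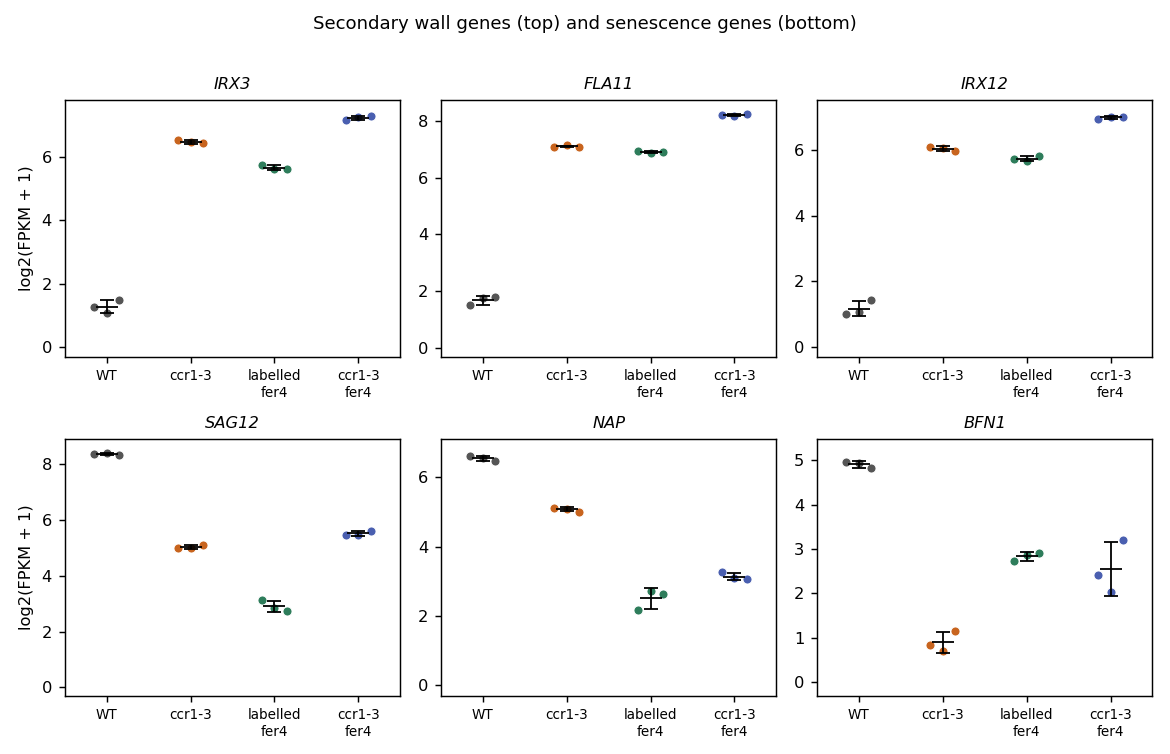
FPKM of 3 secondary wall and lignin genes (top) and 3 senescence genes (bottom) on the log2(FPKM + 1) scale in the 12 libraries, with bars for the mean and SD of each genotype. IRX3 has a mean of 1.44 FPKM in WT and of 86.9, 49.2 and 148 in ccr, the libraries labelled fer and ccrfer, and SAG12 one of 327 in WT against 31.6, 6.52 and 44.9.

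The comparison of ccrfer with ccr asks what the FERONIA mutation alters in the ccr1-3 background. Salicylic acid genes fell steeply. PR1 went from 30.8 ± 2.15 in ccr to 0.674 ± 0.584 in ccrfer (log2 difference -4.32, adjusted p = 2.42e-07, lower in 3 of 3 libraries), PR5 from 711 ± 32.6 to 101 ± 22.1 (-2.83), and NIMIN1, a repressor in the same pathway, from 11.4 to 0.215 (-3.38). PAD3 and CYP71A13, enzymes of camalexin synthesis, fell by 2.24 and 2.83 on the log2 scale, the touch-induced wall gene TCH4 went from 33.4 ± 1.98 to 2.42 ± 1.45, and the cadmium resistance gene PCR1 from 43.0 to 0.377 (-5.04). Jasmonate genes rose, with VSP1 at 0.995 in ccr and 30.1 in ccrfer (3.96), LOX2 at 6.91 ± 0.301 and 70.1 ± 1.32 (3.17) and VSP2 at 129 and 803. Outside genes listed at 0 in a genotype, the largest increase was that of PYK10, a beta-glucosidase of endoplasmic reticulum bodies (2.07 ± 0.142 to 90.9 ± 1.03, log2 difference 4.91).

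Of 29 salicylic acid genes 27 fell in ccrfer and none rose (median -1.32, camera adjusted p = 1.22e-24). Pattern-triggered immunity fell in 16 of 28 genes with none higher (adjusted p = 3.82e-10), including the receptor gene RLP23 (23.0 to 5.13 FPKM). Calcium sensors and channels fell in 19 of 29 with 2 higher (adjusted p = 7.62e-11), with CML37 at -2.31. Cysteine-rich receptor-like kinases (11 of 20 lower and 3 higher, adjusted p = 0.000161), wall-associated kinases (7 of 13 lower, 8.25e-05) and abscisic acid, cold and drought genes (11 of 21 lower and 3 higher, 0.000624) fell too, among them CRK37 (-2.04), WAK1 (111 ± 4.32 to 42.8 ± 4.44) and RD26 (-2.86). Glucosinolate biosynthesis rose in 18 of 20 genes with 2 lower (median 0.80, adjusted p = 2.9e-11), for example CYP79F1 (385 to 772 FPKM). Secondary wall genes rose again in 18 of 24 (median 0.75, adjusted p = 1.02e-10), with XCP2, a protease of xylem cell death, at 1.63 and FLA11 at 292 FPKM against 136. Flavonoid and anthocyanin genes rose in 11 of 15 (adjusted p = 6.19e-10), MYB90 by 1.98, jasmonate genes in 10 of 20 with 1 lower (3.78e-06) and epidermis markers in 5 of 8 (2.57e-05). Lignin biosynthesis rose in 12 of 24 with 1 lower (adjusted p = 3.75e-05), with LAC11 at 1.91, and phloem markers in 3 of 9 (0.0147). These calls were lost for lignin (adjusted p = 0.153 with an estimated correlation) and for phloem (adjusted p = 0.227 with an estimated correlation). The phloem call also ended without ccrfer replicate 1 (0.0601) or 2 (0.0832).

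Senescence (2 higher and 5 lower of 15, adjusted p = 0.164), photosynthesis (5 higher and 3 lower of 30, 0.566), primary wall and cell expansion (7 higher and 3 lower of 15, 0.473), pectin modification (3 higher and 1 lower of 10, 0.131), ethylene-jasmonate defence (2 higher of 5, 0.108), heat shock (1 higher and 4 lower of 7, 0.131), cambium markers (3 higher and 1 lower of 7, 0.0997), seed and silique markers (0 higher and 1 lower of 10, 0.101) and FERONIA family and partners (1 higher and 2 lower of 14, 0.416) were not called between ccrfer and ccr. Photosynthesis passed the threshold without ccrfer replicate 3 (0.00733), and seed and silique markers with a pseudocount of 0.1 (0.00221). Adjusted over the list alone, more members passed for secondary wall (21 higher and 1 lower), lignin (13 higher), flavonoid (13 higher), salicylic acid (28 lower), pattern-triggered immunity (18 lower), cysteine-rich kinases (12 lower), calcium (21 lower), jasmonate (12 higher and 2 lower), ethylene-jasmonate defence (3 higher and 1 lower), pectin (2 lower), heat shock (2 higher), photosynthesis (6 higher), cambium (4 higher) and epidermis (6 higher), and for seed markers none did.

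In all, 1912 genes were called higher and 1857 lower in ccrfer than in ccr, 393 and 485 of them by at least 2-fold. With median-of-ratios scaling the lower genes were more numerous (1857 higher and 1925 lower). The libraries did not overlap for 6998 genes (38.0%), against 10% by chance. Leaving out any single ccr or ccrfer library gave 2641 to 4297 called genes, the highest without ccrfer replicate 2. With the level of AT2G01021 as a covariate, a fit chosen after the data were seen, 2310 genes were called, 2082 of them also called without it.

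Of the 4416 genes higher in ccr than in WT, 821 (18.6%) were lower in ccrfer than in ccr, 688 (15.6%) were higher again and 2907 had no call. In ccrfer, 3270 (74.0%) of the 4416 remained above WT. The balance was the other way among the 1181 genes at least 2-fold higher in ccr than in WT. Of these, 247 (20.9%) were lower in ccrfer than in ccr and 318 (26.9%) higher again, and 84.2% remained above WT. The 821 genes had a median difference of 0.75 between ccr and WT, -0.63 between ccrfer and ccr and 0.04 between ccrfer and WT, and in ccrfer 228 were still above WT, 162 below and 431 without a call. Against the libraries labelled fer their median was -0.37 in ccrfer, with 428 called lower and 102 higher. The ccrfer libraries had also served to choose these genes, which by itself lowers this median. Without ccr replicate 1 the count was 495, and with the AT2G01021 covariate 505. All 14 salicylic acid genes that were up in ccr, among them PR1, PR5 and NIMIN1, were lowered in ccrfer (Fisher's exact test among the genes up in ccr, adjusted p = 1.18e-09), as were 8 of 11 pattern-triggered immunity genes, 7 of 9 calcium genes and 6 of 7 abscisic acid, cold and drought genes (0.00132 for each). None of the 22 secondary wall genes up in ccr was lowered, and 18 were higher again (0.102 for the count lowered). Fisher's test takes genes as independent, which members of a list measured in the same libraries are not. Its p values here and in the next paragraph may be too small. WRKY40 (AT1G80840), a regulator of immune genes, went from 3.31 in WT to 13.0 in ccr and 2.59 in ccrfer, and HAI1, a phosphatase of abscisic acid signalling, from 1.25 to 16.3 and 3.58.

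Of the 3642 genes lower in ccr than in WT, 619 (17.0%) were raised in ccrfer, 406 fell again, and 2787 remained below WT. FSD1 returned from 0.596 ± 0.269 in ccr to 35.5 ± 6.98 in ccrfer, against 75.5 ± 3.25 in WT. Flavonoid and anthocyanin genes were raised in 9 of the 11 that were down in ccr (Fisher's exact test, adjusted p = 9.83e-05), including MYB90 (93.8, 9.26 and 39.6 FPKM in WT, ccr and ccrfer), and glucosinolate genes in 4 of 5 (0.0394). Since both comparisons use the ccr libraries, chance alone moves them apart. Independent lists of these sizes would give 445 genes up and then lowered and 378 down and then raised. In 100 simulations with no effect there were at most 1 and 0, but these hold almost no calls and do not show what sharing adds to real effects. Independent lists would give 458 genes up and higher again, where 688 were found, and 367 down and lower again, where 406 were found. Counts in the same direction thus also lay above those of independent lists. The correlation of the ccr minus WT and ccrfer minus ccr differences across genes was -0.149, and their covariance -0.0611 against -0.0215 in the simulations, a difference of -0.0396. No split of the 3 ccr libraries leaves 2 for each comparison, and none was run. Part of the excess may come from their being shared.

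**Figure D3:**
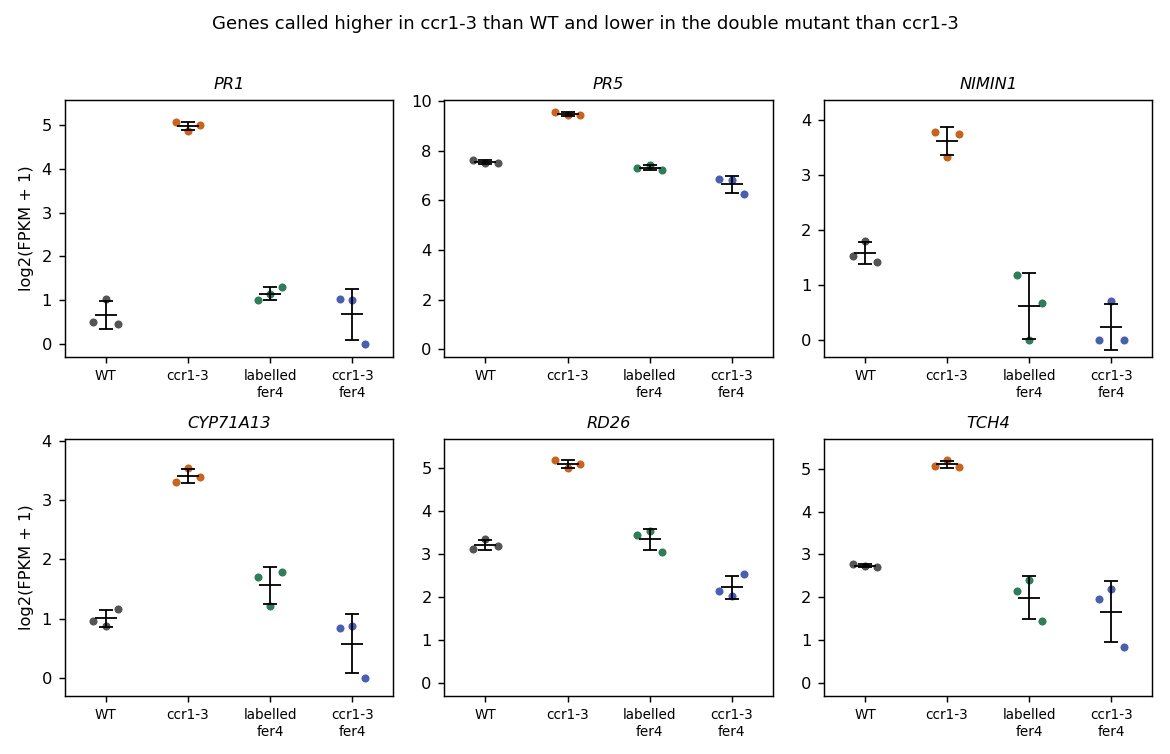
FPKM of genes called higher in ccr than in WT and lower in ccrfer than in ccr, on the log2(FPKM + 1) scale in the 12 libraries, with bars for the mean and SD of each genotype. PR1 has means of 0.608, 30.8, 1.22 and 0.674 FPKM in WT, ccr, the libraries labelled fer and ccrfer.

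The authors' deposited table listed 313 genes, each with a log2 ratio of ccr to WT of at least 1.00 and a lower mean in ccrfer. Of the 310 that were tested, limma called 297 higher in ccr than in WT, 249 lower in ccrfer than in ccr, and 246 (79.4%) both. Of the 821 genes with both limma calls, 298 had a ratio of means of 2 or more, and 52 of these were not in the table. PR1 lay on chromosome 2 from 6241704 to 6242463 of TAIR10 in the authors' deposited table, with a log2 ratio of 5.67 and adjusted p of 0.000266 in both of the authors' comparisons. TCH4 was placed on chromosome 5 from 23307130 to 23308282, P5CS1 on chromosome 2 from 16598164 to 16603319, and WRKY40 on chromosome 1 from 30383691 to 30385499, in the authors' deposited table. The gene with the highest ratio there, AT1G73600, a methyltransferase gene with a log2 ratio of 6.62, rested on a single library. AT1G73600 was at 2139 FPKM in ccr replicate 2, at 19.5 and 17.5 in the other ccr libraries and at 6.92 to 31.4 in the other 9. limma called it in neither comparison (adjusted p = 0.0543 and 0.341). The auxin conjugation gene GH3.3 followed with 5.67. By the authors' categories, 73 of the 313 genes were not assigned, 47 fell under RNA, 29 under protein, 18 under stress, 15 under hormone metabolism and 14 under cell wall.

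The comparison of the libraries labelled fer with WT asks what the FERONIA mutation alters while CCR1 is intact. Because FER was at the WT level in these libraries, the directions given here belong to the libraries labelled fer. Jasmonate genes were far higher there, with VSP2 at 1905 ± 34.9 against 16.2 ± 0.341 in WT (log2 difference 6.79), LOX2 at 216 against 2.51 (5.95), VSP1 at 25.8 against 0.654 (4.02) and the repressor gene JAZ10 at 27.1 against 1.24 (3.63). Secondary wall genes were higher as they were in ccr, with XCP2 at 55.3 ± 2.63 against 0.355 ± 0.0565 (5.38) and FLA11 at 118 against 2.24 (5.20). The seed storage protein gene SESA3 was at 57.9, 56.2 and 68.1 in the libraries labelled fer and listed at 0 in the 3 WT libraries. Single members of the abscisic acid, cold and drought list were far lower, LTI78 at 0.960 against 38.4 (-4.34), DREB1A at 0.139 against 15.4 (-3.86) and COR47 at 42.1 against 336 (-2.97). SAG12 was at 6.52 against 327 (-5.46), and NAP, a senescence regulator, at 4.77 against 92.6 (-4.04).

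In the libraries labelled fer, the higher lists were lignin (24 of 24, median 1.57, camera adjusted p = 5.31e-14), secondary wall (23 of 24, 3.09, 4.5e-14), primary wall (12 higher and 1 lower of 15, 2.93e-05), cambium (7 of 7, 0.000267), jasmonate (16 higher and 2 lower of 20, 2.37e-07), glucosinolate (19 higher and 1 lower of 20, 8e-10), flavonoid (11 higher and 2 lower of 15, 0.00184), heat shock (7 of 7, 0.000228) and seed and silique markers (10 of 10, median 3.67, 8e-10). In ccrfer against WT, 1 of 10 seed and silique markers was higher (median 0.03, camera adjusted p = 0.525). Whether the stems of the libraries labelled fer differed in tissue content was not tested. Heat shock genes included HSP70 at 156 FPKM in the libraries labelled fer against 27.8 in WT. Photosynthesis was higher in 20 of 30 genes and lower in 1 (adjusted p = 0.00011), with LHCB2.2 at 302 against 55.8, a list call lost otherwise (adjusted p = 0.357 with an estimated correlation). The lower lists were senescence (12 of 15 with 1 higher, adjusted p = 7.5e-07), cysteine-rich receptor-like kinases (16 of 20 with 2 higher, 8.29e-05), wall-associated kinases (10 of 13, 0.000175), calcium (18 of 29 with 4 higher, 0.000329), abscisic acid, cold and drought (13 of 21 with 5 higher, 0.00158), salicylic acid (16 of 29 with 5 higher, 0.00345) and pattern-triggered immunity (14 of 28 with 5 higher, 0.0182). FLS2, the flagellin receptor gene, was at -2.03 on the log2 scale. Epidermis markers (6 higher and 1 lower of 8, 0.0519), which passed without any single library labelled fer (0.0349 to 0.0446) and under 5 other alternatives by camera (0.0387 to 0.0476), phloem markers (4 higher and 4 lower of 9, 0.646), pectin modification (2 higher and 2 lower of 10, 0.396), ethylene-jasmonate defence (3 higher and 2 lower of 5, 0.716) and FERONIA family and partners (4 higher and 3 lower of 14, 0.88) were not called.

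The libraries labelled fer had 5237 genes called higher and 4281 lower than WT, and those libraries did not overlap for 11677 genes (63.4%, against 10% by chance). After quantile normalization 4630 were higher and 4761 lower. Adjusted over the list alone, the member counts rose to 13 higher and 2 lower for primary wall, 7 higher and 15 lower for pattern-triggered immunity, 17 lower for cysteine-rich kinases, 19 lower for calcium, 14 lower for abscisic acid, 21 higher for photosynthesis and 2 lower for epidermis. Both ccr and the libraries labelled fer were higher than WT for 3006 genes, and both were lower for 2412, where independent lists would give 1255 and 846. Simulations with no effect gave at most 0 and 1. They hold almost no calls, so they do not show how much overlap the shared WT libraries add to real effects, and part of the excess may come from them. The correlation of these differences was 0.651, against a mean of 0.504 in the simulations from the shared libraries. The covariance was 0.430, against a simulated covariance of 0.0216. Between comparisons that share no library, fer minus WT and ccrfer minus ccr correlated across genes at r = 0.276 (rho 0.168, genes not being independent replicates). For these, 1095 genes were higher in both, 801 lower in both and 907 opposite, against 543 and 431 expected of independent lists for the first counts. For ccr minus WT and ccrfer minus fer, which share no library either, r was 0.113 (rho 0.085). There 1306 genes were higher in both, 1070 lower in both and 1886 opposite, against 851 and 777 expected for the first counts. No expectation was computed for the opposite counts of either pair. The excess in the same direction therefore does not by itself show agreement.

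The comparison of ccrfer with the libraries labelled fer sets the double mutant beside libraries in which FER was at the WT level, so its directions too rest on the libraries labelled fer. The sugar phosphate translocator gene GPT2 was at 67.3 ± 3.07 in ccrfer against 2.56 ± 0.0429 (log2 difference 4.26), the dehydrin gene LTI30 at 49.4 against 1.88 (4.17), the wax gene CER1 at 34.7 against 1.08 (4.14) and the transporter gene UMAMIT14 at 19.7 against 0.227 (4.05). Secondary wall (17 higher and 1 lower of 24, camera adjusted p = 6.19e-08) and abscisic acid, cold and drought genes (14 higher and 3 lower of 21, 0.00035) were higher in ccrfer. Lower were seed and silique markers (9 of 10, 7.63e-12), heat shock (6 of 7, 0.000113), jasmonate (15 of 20 with 1 higher, 1.19e-06), glucosinolate (14 of 20, 1.55e-05), salicylic acid (19 of 29, 2.26e-05), flavonoid (11 of 15 with 2 higher, 2.26e-05) and calcium (13 of 29 with 3 higher, 0.00714). Lignin was called higher (10 with 2 lower of 24, 0.00714), and photosynthesis (29 of 30, 9.43e-12), pattern-triggered immunity (10 with 2 higher of 28, 0.0482) and phloem (5 of 9, 0.0289) were called lower. For these the adjusted p with an estimated correlation was 0.308, 0.143, 0.0941 and 0.308, and the calls were lost. The remaining lists had adjusted p of 0.0862 or more. Among them, epidermis markers passed after quantile normalization (0.0486) and without fer replicate 3 (0.0346), and cysteine-rich kinases without ccrfer replicate 3 (0.0425). Adjusted over the list alone, the counts of called lists differed for lignin (3 lower), salicylic acid (20 lower), pattern-triggered immunity (3 higher and 11 lower), glucosinolate (15 lower) and abscisic acid (4 lower). In all, 3551 genes were called higher and 3930 lower in ccrfer than in the libraries labelled fer, and 7921 (43.0%, against 10% by chance) did not overlap. After quantile normalization 3939 were higher and 3616 lower. With only these 6 libraries in the fit, 4380 genes were called.

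In ccrfer against WT, 4596 genes were called higher and 4207 lower, and the libraries did not overlap for 10240 (55.6%, against 10% by chance). The balance turned with median-of-ratios scaling (4255 higher and 4625 lower). MLP28 (1.42 ± 0.686 to 629 ± 45.7, log2 difference 8.06) and TGG2 (0.518 to 242, 7.38) rose most among the genes not listed at 0 in a genotype. Secondary wall (22 of 24 higher, median 3.85, camera adjusted p = 1.11e-17), lignin (22 of 24, 5.61e-16), primary wall (13 higher and 2 lower of 15, 2.8e-07), cambium (6 of 7, 0.00011), glucosinolate (15 higher and 3 lower of 20, 6.86e-06), jasmonate (14 higher and 4 lower of 20, 0.000159) and epidermis (6 of 8, 0.00153) were higher than in WT. Salicylic acid (22 of 29 lower and 1 higher, 1.02e-07), calcium (22 of 29 with 2 higher, 7.99e-07), senescence (12 of 15 with 1 higher, 1.77e-06), cysteine-rich kinases (15 of 20 with 2 higher, 3.1e-06), wall-associated kinases (12 of 13, 3.1e-06), pattern-triggered immunity (19 of 28 with 3 higher, 1.65e-05) and photosynthesis (15 of 30 with 3 higher, 0.0456) were lower. The jasmonate, epidermis and photosynthesis calls were lost (adjusted p = 0.086, 0.086 and 0.729 with an estimated correlation). Adjusted over the list alone, the counts of called lists differed for secondary wall (23 higher), cysteine-rich kinases (17 lower) and calcium (23 lower).

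Of the lists called with the preset correlation, 7 of 8 held with an estimated correlation in ccr against WT, 11 of 13 in ccrfer against ccr, 16 of 17 in fer against WT, 9 of 13 in ccrfer against fer and 11 of 14 in ccrfer against WT. In ccr against WT and in ccrfer against ccr, mixed splits of the libraries also called as many lists. The number of called lists there is thus not set apart from mixed groupings. Such splits keep part of the genotype difference, so they do not show that the lists were called by chance. The lists whose median, mean and test differed in sign, such as abscisic acid in ccr against WT (median -0.06, mean 0.29, test up), heat shock there (-0.15, 0.20, down), primary wall in ccrfer against ccr (0.17, -0.14, up) and senescence there (0.07, -0.32, down), were not called in the comparison concerned. In 124 tested genes all 3 libraries of a genotype were listed at 0. Of these, 10 had a mean FPKM of 100 or more in another genotype, as did CAT3 (AT1G20620), a catalase gene listed at 0 in the 3 WT libraries and at 2522 to 3428 in the other 9. Whether such a 0 stands for an absent transcript or for an estimate that failed was not recorded in the labels, so calls of these genes are uncertain.

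**Figure D4:**
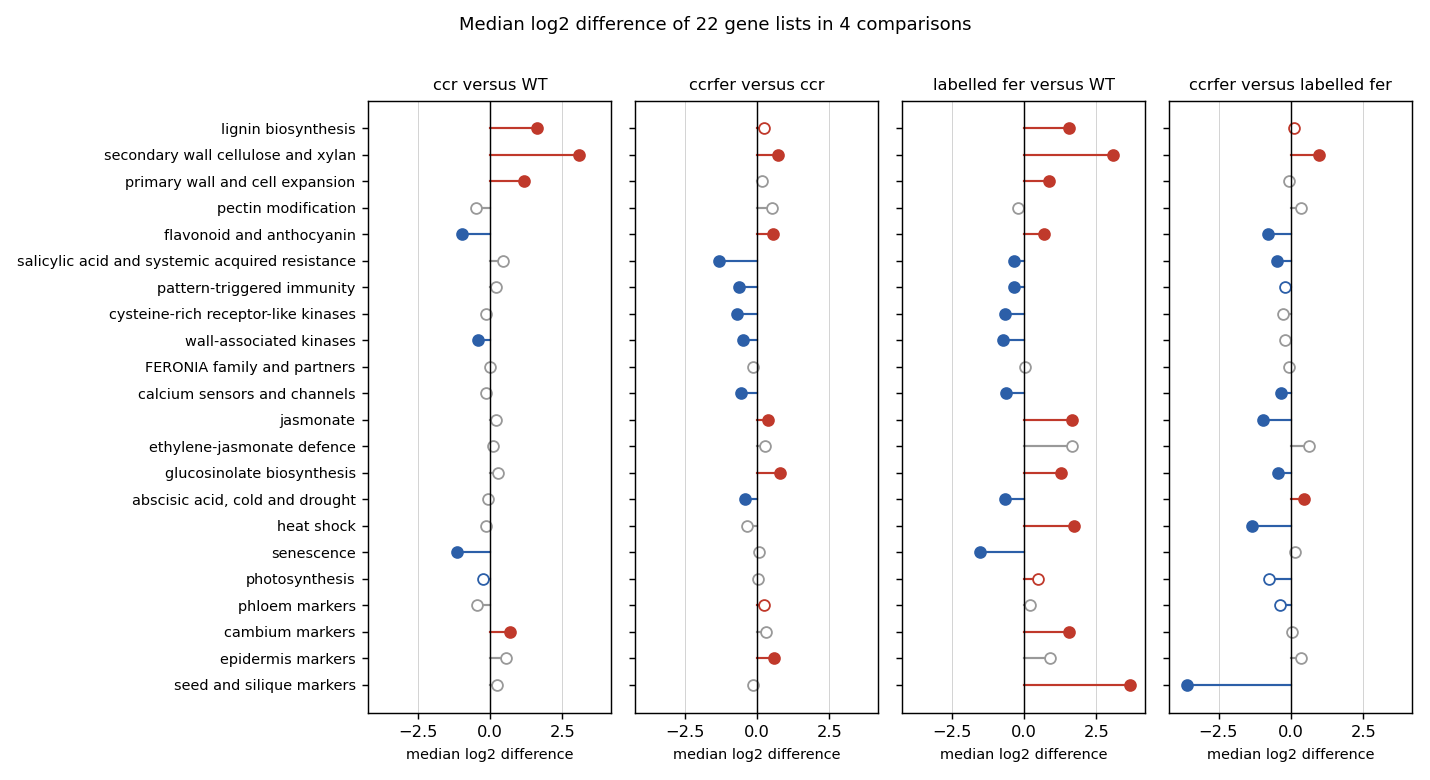
Median log2 difference of each gene list in the comparisons, with red for lists called higher by camera, blue for lists called lower, grey for lists not called, and filled points for calls that also hold with an estimated correlation. The salicylic acid list has a median of 0.44 in ccr against WT and of -1.32 in ccrfer against ccr, and the secondary wall list of 3.08 and 0.75.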

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

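The tests of FER in ccrfer, of DGAT2, of single WT libraries, of the cambium markers and of ccrfer replicate 3 were chosen only after the results they concern had been seen, and the other tests here were planned.

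The interaction test asked whether the ccrfer minus fer difference departs from the ccr minus WT difference. FER was nearly absent from ccrfer alone of the 4 genotypes. It called 7270 genes, 3149 higher and 4121 lower. Among 100 splits of the 12 libraries, 1 gave as many interaction genes, the real split, and the highest other split gave 2251. Mixed groups carry differences between genotypes in their spread, which lowers their counts. The share, under 0.05, thus reflects how alike the libraries of a genotype were and does not test the interaction itself. FER had an interaction of -5.81 on the log2 scale. SAG12 (327 FPKM in WT, 31.6 in ccr, 6.52 in the libraries labelled fer and 44.9 in ccrfer) had one of 5.95, and MLP28 (1.42, 90.2, 2684 and 629) one of -7.36.

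Several genes with a called interaction were listed at 0 in every library of a genotype, so no fold is given. It is not recorded whether these zeros are absent transcripts or estimates that failed, and the calls are uncertain for that reason. The plastid genes ATCG00340 (adjusted p = 1.81e-14) and ATCG00350 (2.4e-15) were listed at 0 in the 3 ccr libraries and at 3951 to 5623 and 3589 to 4540 in the other 9, and AT2G07698 (4.98e-15) at 0 in ccr and 538 to 703 elsewhere. ATCG00490 (1.16e-15) and RR3 (7.25e-15) were at 23189 to 25828 and 6146 to 7092 in the libraries labelled fer and at 0 in the other 9. CAT3 (AT1G20620, 5.94e-14) was listed at 0 in WT and at 2522 to 3428 in the other 9. AT4G03157 (5.56e-06) was at 54.9, 57.2 and 103 in WT, at 2.06 in ccr replicate 2 and at 0 in the other 8. SESA3 (8.23e-09) was at 0 in WT, 0.312 to 1.06 in ccr, 56.2 to 68.1 in the libraries labelled fer and 0 to 0.505 in ccrfer.

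By the camera test of the interaction, senescence was higher (10 of 15 genes higher and 2 lower, adjusted p = 0.000224) and 10 lists were lower. These were lignin (22 of 24 lower, 2.35e-12), secondary wall (20 of 24, 6.5e-13), seed and silique markers (10 of 10, 2.17e-11), jasmonate (14 of 20 with 2 higher, 5.9e-05), glucosinolate (16 of 20 with 2 higher, 5.96e-05), primary wall (11 of 15 with 1 higher, 8.4e-05), salicylic acid (19 of 29 with 3 higher, 0.000103), heat shock (5 of 7, 0.000397), photosynthesis (15 of 30, 0.00173) and cambium (6 of 7, 0.00508). The primary wall, jasmonate and photosynthesis calls were lost (adjusted p = 0.0545, 0.0723 and 0.524 with an estimated correlation). Adjusted over the list alone, the counts differed for secondary wall (22 lower), heat shock (6 lower) and photosynthesis (2 higher and 17 lower). For secondary wall and lignin genes, which were higher in each mutant than in WT, a negative interaction means that the differences of ccr and of the libraries labelled fer from WT did not add up in ccrfer.

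FER was at the WT level in the libraries labelled fer while DGAT2, 3 genes away, was nearly absent there. A transcript that the insertion leaves in every carrier was argued against, since the highest FER value in ccrfer was 1.78% of the mean of the libraries labelled fer. WT or ccr plants in their place were argued against too, since the highest DGAT2 value there was 1.54% of the WT mean. Plants of another genotype with intact FER could not be told apart from fer4 plants by the correlation of fer minus WT with ccrfer minus ccr (r = 0.276), because WT differed from every mutant. DGAT2 and AT3G51530 had means of 0.125 and 0.0105 in the libraries labelled fer, against 24.3 and 6.47 in WT. Both were nearly absent from ccrfer too, which argues against genotypes that express these neighbours of FER. AT3G51560, on the other side, had means of 3.88 in the libraries labelled fer and 0.0286 in ccrfer. A genotype with intact FER that lacks DGAT2 and AT3G51530 stays open. A transcript made from the insertion in the single mutant alone may also account for the pattern, and the reads over FER that would show it were not analysed here.

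Secondary wall genes were lower and senescence genes higher in WT than in all 3 mutants, with senescence medians of -1.15, -1.51 and -1.40 in ccr, the libraries labelled fer and ccrfer. Sharing of the WT libraries had a planned test, the number of genes called alike in the other 3 genotypes. That number was 4579 against WT and 3163 against the libraries labelled fer, a ratio of 1.45. It lay under the limit of 1.5 set beforehand, so the planned test came out on the side of sharing. The libraries labelled fer also stood apart from the others, which raises their count, so this ratio cannot decide the question. Among the WT libraries, the SD of a member was at most 0.346 in the secondary wall list and 0.116 in the senescence list (log2). The median ccr minus WT differences were 3.08 and -1.15. These values, not planned as a test, argue against sharing for these lists unless the WT libraries erred together. Separate errors of single WT libraries were argued against. With any WT library taken alone, the medians of the secondary wall and senescence lists in the 3 mutants were at least 93.0% of those with all 3 WT libraries. An error common to the 3 WT libraries was not tested and stays open. Scaling was argued against, since the median was 2.92 after quantile normalization. A later developmental stage of the WT stems may contribute, as the cambium markers were also lower in WT, by medians of 0.71, 1.56 and 1.60. The labels give all plants the same age, so stage stays open beside an effect of the mutations, which was not tested apart from it.

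ccrfer replicate 3 stood apart from the other ccrfer libraries, with 9582 genes listed at 0 against 7101 and 6242. A lower total depth was argued against, since 7 libraries had fewer mapped reads than ccrfer replicate 3. Mapped reads include those on AT2G01021, so this count cannot show the depth left for other genes. The 1st percentile of FPKM above 0 was highest in this library (0.543), and a lower depth over other genes stays open. A wrong genotype label in that library was argued against, since its FER was 1.78% of the WT mean (1.775%). Ribosomal RNA taking reads from low genes could be a source, but within genotypes the number of genes at 0 and log10 AT2G01021 FPKM gave r = 0.825 over 12 libraries with p = 0.0941 (exact permutation of libraries within genotypes, 1296 permutations, two-sided), rho = 0.587 with p = 0.18, and r = 0.647 without ccrfer replicate 3 and fer replicate 2. A biological difference of that plant sample was not tested.

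In the comparisons of 3 with 3 libraries, the 10 splits are too few for a share under 0.05. For genes changed in ccr versus WT, 1 split gave as many (8058, highest other 1). The same number, 1, was found for ccrfer versus ccr (3769, highest other 0), fer versus WT (9518, 0), ccrfer versus fer (7481, 5) and ccrfer versus WT (8803, 1). For gene lists changed, 5 splits gave as many in ccr versus WT (8, highest other 9), 4 in ccrfer versus ccr (13, 13), 1 in fer versus WT (17, 14) and 1 in ccrfer versus fer (13, 5). In ccr versus WT and in ccrfer versus ccr the share lay far over 0.05. Each mixed split still held unequal numbers of the genotypes in its groups, so part of the genotype difference stayed in it. Camera sets a list against other genes and can call it from that part. The shares for list counts therefore cannot decide whether a random grouping is their source. For the genes up in ccr versus WT and lower in ccrfer versus ccr, 2 of 100 splits gave as many (821, highest other 2480). For those down and then higher, 2 of 100 did (619, 2976). These shares lie under 0.05, but nearly all mixed splits called almost none of these genes, as their spread holds differences between genotypes. The shares therefore do not test the reversal. The other split in both cases placed the 3 WT libraries in the ccr group, which both comparisons share. The next split, with 245 and 145 genes, kept the 3 ccr libraries together in that group. A split that kept the WT libraries as WT and mixed the others gave 0 and 0. What drives these counts was not tested.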

How the results depend on the processing

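Of the alternatives, library weights, the AT2G01021 covariate, the FPKM minimum of 5, the removal of genes listed at 0 and the removal of the libraries labelled fer were chosen after seeing the data. Gene counts stayed within 1.5 times the reported ones in 138 values and left that range in 14, and list counts stayed in 50 and left it in 2. With a minimum log2 difference of 1, by construction fewer genes were called: 2086 in ccr versus WT, 878 in ccrfer versus ccr, 3088 in fer versus WT, 1537 in ccrfer versus fer, 2757 in ccrfer versus WT, 3137 in the interaction, 146 up in ccr and lower in ccrfer, and 73 down and then higher. Only the compared genotypes gave 4380 genes in ccrfer versus fer, 2715 in ccrfer versus ccr and 7623 in ccrfer versus WT, but more than the main fit in ccr versus WT (11850) and fer versus WT (10102). Library weights, with 0.105 for ccrfer replicate 3, gave 12323 genes in ccr versus WT and 1025 down and then higher. The AT2G01021 covariate gave 2310 in ccrfer versus ccr and 505 up and then lower, 452 of them shared. The main fit used a common spread for all genotypes, while libraries correlated at 0.991 to 0.993 in WT and ccr and at 0.938 to 0.983 in ccrfer. Its adjusted p values may thus be too large in ccr versus WT and too small in comparisons with ccrfer. The counts with only the compared genotypes moved that way, although fewer libraries also lower counts. The cause of these shifts was not tested further. fry called 20 lists in ccr versus WT and 20 in ccrfer versus fer, as it sets no list against other genes. It reversed ethylene-jasmonate defence in ccrfer versus fer (0.0256), a list not called by camera.

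Leaving out a library each time gave 6649 to 6854 genes in ccr versus WT, 2641 to 4297 in ccrfer versus ccr, 8239 to 8995 in fer versus WT, 6800 to 8179 in ccrfer versus fer, 7458 to 9497 in ccrfer versus WT and 6244 to 8415 in the interaction. It gave 495 (without ccr replicate 1) to 928 genes up and then lower, 413 to 774 down and then higher, and 8, 12 to 14, 17 to 18 and 12 to 14 lists in ccr versus WT, ccrfer versus ccr, fer versus WT and ccrfer versus fer. With the replicate block, 7898, 3650, 9371, 7315, 8688 and 7113 genes were called in the comparisons and the interaction, 788 up and then lower and 587 down and then higher.

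No named gene that was called in the main fit or in an alternative changed direction between them, and directions of uncalled genes were not compared. Of 339 gene results, 318 kept their side of the threshold under every alternative run on them. Calls lost on leaving out a library were those of AT2G45220, GSTF11, CLE44, HSP17.4, SESA3 and SESA4 in ccr versus WT, and of HSP18.2, AT5G02070, WAKL2, RALF23, HCHIB, RBCS3B, ATHB-15, SEOa, LHCB2.3 and SESA4 in ccrfer versus ccr. EXPA15 in ccrfer versus ccr lost its call with a pseudocount of 0.1 (adjusted p = 0.0643). Of 88 list results, 51 kept their side throughout, and phloem in ccrfer versus ccr and in ccrfer versus fer and pattern-triggered immunity in ccrfer versus fer lost their call on leaving out a library. Scaling moved the median of all genes by at most 0.068 (log2) and turned the direction of no called list and of no called named gene. It did turn the balance of higher and lower genes. With median-of-ratios scaling 4255 were higher and 4625 lower in ccrfer versus WT, and 1857 and 1925 in ccrfer versus ccr. After quantile normalization there were 4316 and 4351, and 1928 and 1962, in these comparisons, 4630 and 4761 in fer versus WT, and 3939 and 3616 in ccrfer versus fer. The 1st percentile of FPKM above 0 was highest in ccrfer replicate 3 (0.543), where low genes were measured least finely. Next came fer replicate 2 (0.245), fer replicate 3 (0.160), ccrfer replicate 1 (0.0938) and fer replicate 1 (0.0405), the order of their AT2G01021 FPKM. The other libraries lay between 0.0207 and 0.0363. Low genes were thus measured less finely in these libraries than in those of WT and ccr. Reads lost to AT2G01021 may account for this order, which was not tested.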

Other observations

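A set of genes was high both in the libraries labelled fer and in ccrfer and low in WT and ccr. They were chosen for this pattern after their values were seen, as those with means of 5 or more in the libraries labelled fer and in ccrfer, each over 10 times the WT and the ccr mean, and limma calls in fer against WT and in ccrfer against ccr. There were 17 such genes, 2 of them listed at 0 in WT and ccr. The beta-glucosidase gene BGLU18 had mean FPKM of 37.9 in WT, 47.0 in ccr, 526 in the libraries labelled fer and 579 in ccrfer. PYK10 was at 1.96 ± 0.388, 2.07 ± 0.142, 76.7 ± 3.27 and 90.9 ± 1.03 (SD, n = 3), NAI2, which is needed to form endoplasmic reticulum bodies, at 1.19, 1.52, 24.5 and 24.6, and the jacalin-related lectin gene JAL33 at 0.365, 0.839, 32.8 and 20.3. PYK10, NAI2 and JAL33 are known from endoplasmic reticulum bodies and their protein complexes, but no list of such genes was fixed or tested for enrichment. LOX2, VSP1 and ARGAH2, known to respond to jasmonate, were among the 17. Lower by the same rule were only DGAT2 and AT3G51530, both near FER.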
